A study of Arabidopsis thaliana with 16 samples.

How the data were processed

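Gene expression was measured on Affymetrix ATH1 arrays, which carry short probes grouped into probe sets, in 4-day-old Arabidopsis seedlings of a line in which the transcription factor FHY3 is replaced by FHY3 fused to the hormone-binding part of the glucocorticoid receptor (GR), expressed from the FHY3 promoter in the fhy3-4 mutant. The fusion protein stays in the cytoplasm until the steroid dexamethasone (DEX) is given and then enters the nucleus. Per the labels, seedlings were kept in darkness or continuous far-red light, then given 10 µM DEX or the ethanol solvent (mock) for 2 h. The 16 arrays fall into 4 groups of 4, which the series' design text calls independent biological replicates. Groups and replicate numbers were taken from the sample titles, and 0 columns of values were left unused.

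The deposited values are log2 signals per probe set, already summarised and normalised by the authors. RMA and the affy package are named in the submitters' processing notes without versions or settings, and the probe set definitions and filters are not given in the sources used here. Array medians ran from 6.60 to 6.68 on the log2 scale, so the arrays had been brought to nearly the same level before deposit, and a change of all transcripts together would not be seen. The files give no background or detection call, so the precision rests on the 4 arrays per group.

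The file holds 22810 probe sets. The 64 control probe sets of the manufacturer were left out, and 22746 were tested. Of these, 13513 (59.4%) are paired with 1 gene in the annotation used here, 503 with several genes, and 8730 are unnamed here. For 13436 of the 13513 the gene ID matched the RefSeq table of the TAIR10.1 assembly, which was used for names only, so no coordinates are given. Of the single-gene probe sets, 88.3% carry a locus tag and no symbol. Probe sets with several genes or none enter the counts and are never named.

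One linear model over all 16 arrays, with a mean per group and no other term, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), which gave 19.65 degrees of freedom including the prior. The moderated two-sided test was used for DEX against mock in dark and in far-red, far-red against dark under mock and under DEX, and the difference of the DEX response between far-red and dark. P values were adjusted by Benjamini and Hochberg over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05. Every adjusted p of a gene in the text comes from this fit unless an alternative is named beside it, and ± is the standard error of a log2 change or, where stated, the SD of 4 arrays. The DEX contrasts in dark and in far-red share no array. Each light contrast shares arrays with the DEX contrasts.

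These choices were made before the data were examined: the model, the comparisons, the alternatives, the gene lists and the rule for naming genes. The rule takes, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among called single-gene probe sets, with the brightest probe set for each gene, up to 4 members of each list with the smallest p, and 11 genes always. Of those 11, only FHL and HEMB1 are paired with a probe set here; the other 9, FHY3 among them, are not analysed here, so the level of the targeted gene could not be used to check the labels. Single-gene probe sets of the same gene were compared for 146 genes: their calls differed for 3 of them for DEX in dark, 1 for DEX in far-red, 52 for light under mock, 52 for light under DEX and 0 for the difference of responses, and called probe sets of 1 gene never had opposite directions.

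Of the 19 gene lists fixed beforehand, with 284 loci, only 39 loci were paired with a single-gene probe set, and 5 symbols were left out because the reference pairs their locus with another symbol. The 7 lists with at least 3 measured members were tested. A further 22 lists, mostly gene families, were added after the annotation had been seen and before any group was compared, of which 20 could be tested. Lists were tested with camera (preset correlation 0.01) against the 13356 genes with a single-gene probe set, with Benjamini and Hochberg adjustment over the 27 lists of each comparison. Camera with a correlation estimated from the data and fry, which asks only whether a list's genes move one way, were run beside it. For the lists fixed beforehand, members were also adjusted over the list alone. A pair of lists of seed maturation and low-oxygen genes was written from memory of the literature after the named genes had been seen. The pair was tested on the members not seen before, in the same arrays. Of 46 seed maturation and 47 low-oxygen genes listed, 28 and 26 were measured.

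The model was tested on simulated data with the real arrays' means and spread. Of 100 probe sets changed by 0.5 on the log2 scale, 91 were recovered for DEX in dark, 81 for DEX in far-red, 86 for light under mock, 81 for light under DEX and 53 for the difference of responses, and of 100 changed by 1 log2 unit, 100, 99, 100, 100 and 99. Among the unchanged probe sets 7, 10, 6, 8 and 12 were called. For DEX in dark, camera with either correlation and fry each called 20 of 20 lists of 10 genes shifted by 0.3 and 0 of 20 unshifted lists. These lists were drawn at random from genes simulated independently of each other. Real lists can be correlated, with an estimate of 0.55 for nuclear photosynthesis. The simulation therefore does not show how often camera with the preset correlation calls such lists wrongly.

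RNA quality was compared between groups with exact two-sided permutation tests of 16 comparisons, on the signal at the 3′ end minus that at the 5′ end of control transcripts and on a ribosomal RNA probe set. Alternatives were centring each array on its median, quantile normalisation, a filter on the dimmest 30% of probe sets, a trended and robust variance prior, array weights, fitting only the groups compared, a replicate block, only unique single-gene probe sets, an adjusted p under 0.1 or a fold change of at least 1.5, the mean of all single-gene probe sets of a gene in the list tests, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9. No seedlings without the GR fusion are among these samples, so a response to dexamethasone itself and one to the fusion protein entering the nucleus give the same values here.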

Results

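RNA was profiled on 16 ATH1 arrays from seedlings carrying the FHY3-GR fusion, grown in darkness or continuous far-red light and given DEX or mock for 2 h, with 4 arrays in each of the 4 groups. FHY3 is a transcription factor of far-red light signalling through phytochrome A, and DEX lets the fusion protein enter the nucleus. Arrays of the same group correlated at 0.9956 to 0.9981, and no 2 arrays held identical values. The first principal component, with 72.3% of the variance, separated far-red from dark arrays. The second, with 7.22%, separated DEX from mock in both lights: the dark DEX arrays lay between -16.37 and -11.3 and the dark mock arrays between 7.27 and 20.33, with dark mock replicate 2 nearest to the DEX arrays. In far-red the DEX arrays lay between -6.59 and -1.88 on it and the mock arrays between 0.01 and 7.79, apart in the same direction. Of the signals at the 3′ end minus the 5′ end of control transcripts, that of ubiquitin was 1.21 ± 0.04 in dark DEX, 1.27 ± 0.01 in dark mock and 1.19 ± 0.05 in far-red mock on the log2 scale (SD, n = 4 each). All dark mock arrays lay above those of both other groups, and each exact permutation p was 0.0286, the smallest that 4 against 4 arrays allow (adjusted p = 0.153 over 16 comparisons). With so few arrays the adjusted test could hardly pass, so it does not show that RNA quality was alike.

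**Figure D1:**
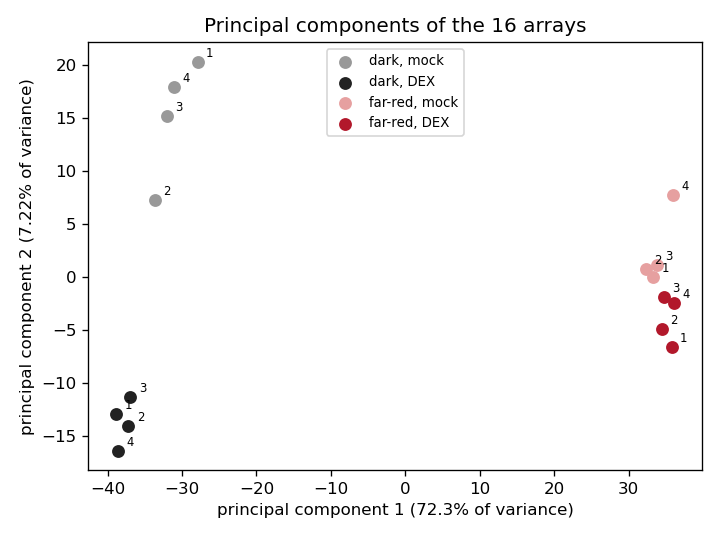
Each point is 1 of the 16 arrays, numbered by replicate and coloured by group, on the first (x) and second (y) principal component of the log2 signals, with their percent of the variance. Far-red and dark arrays lie apart on the first component (72.3%), and DEX and mock arrays lie apart on the second (7.22%) in dark and, less widely, in far-red.

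The first comparison asks which transcripts respond within 2 h to DEX in darkness. AT2G41990 rose most among the named genes, 7.65-fold, from a log2 signal of 5.37 ± 0.36 in mock to 8.31 ± 0.13 under DEX (SD, n = 4 each; log2 change 2.94 ± 0.13, adjusted p = 2.18e-11). AT2G42900 rose 5.13-fold, AT1G22910 2.81-fold and SAG29, also known as the sugar transporter SWEET15, 2.37-fold. Among named genes AT5G42200 fell most, from 10.41 ± 0.47 to 8.12 ± 0.29 (SD, n = 4 each), a log2 change of -2.29 ± 0.17 (adjusted p = 1.98e-08). The vicilin-like seed storage protein genes AT2G28490 and PAP85 fell by 1.95 and 1.69 on the log2 scale, the defensin gene PDF2.1 fell by 1.84 and the beta-glucosidase gene BGLU19 fell by 1.83.

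In all, 1342 of 22746 probe sets (5.9%) were called, 533 higher and 809 lower under DEX. Their log2 changes ran from -4.05 to 2.94, the lowest on a probe set that is not named. The other named genes that rose were AT3G57930 (log2 change 1.72), AT1G11700 (1.39), AT4G35380 (1.36), AT1G77480 (1.14), AT5G12050 (1.13) and AT1G49450 (1.09), and the others that fell were AT1G20310 (-2.06), AT4G02170 (-1.95), AT2G15010 (-1.83), AT2G41730 (-1.66) and AT2G43590 (-1.65). For all 20 genes named by size the 4 DEX arrays lay apart from the 4 mock arrays, which chance gives for 2.86% of genes not chosen by their change, as these were. FHL, which acts with FHY1 to carry phytochrome A into the nucleus and is a known target of FHY3, fell 1.97-fold, from 10.42 to 9.44 (log2 change -0.98 ± 0.13, adjusted p = 2.49e-05). HEMB1, an enzyme of tetrapyrrole synthesis and likewise a known target of FHY3, had a log2 change of -0.03 ± 0.06 (adjusted p = 0.867). These were the only 2 measured of 13 FHY3 targets listed beforehand from the literature, too few for a list test.

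Of the 3 measured touch and rapid stress genes, 2 fell with DEX in dark, over all genes and adjusted over the list alone (camera adjusted p = 0.00103; adjusted p = 0.0926 with an estimated correlation). These were CML38, a calmodulin-like protein gene (log2 change -1.42 ± 0.14), and STZ, the zinc finger gene ZAT10 (-0.82 ± 0.12), while WRKY53 stood at 0.01 ± 0.11. On lists written after the largest changes had been seen, 16 of 21 other low-oxygen genes and 11 of 26 other seed maturation genes fell in the same arrays, where the ubiquitin 3′ minus 5′ signal changed by -0.06 with DEX, with medians of -0.52 (camera adjusted p = 3.33e-28, and 0.00812 with an estimated correlation) and -0.41 (5.41e-15, and 0.0319 with an estimated correlation). None of the 11 measured nuclear genes of photosynthesis was called alone, and their median log2 change was 0.13 (camera adjusted p = 0.0358; adjusted p = 0.809 with an estimated correlation, 0.381 without dark DEX replicate 2 and 0.261 without dark mock replicate 4).

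Among the 5 auxin response genes, 1 fell over all genes, WES1 (GH3.5, which conjugates auxin; -0.62 ± 0.10), and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.862). Of 7 chlorophyll synthesis genes 1 rose, over all genes and adjusted over the list alone: CHLM, a methyltransferase of the pathway (0.22 ± 0.06, adjusted p = 0.0477; camera adjusted p for the list 0.227). No member of the flavonoid (3 genes, camera adjusted p = 0.953), cell wall loosening (4 genes, 0.953), abscisic acid (3 genes, 0.953) or root marker (3 genes, 0.227) lists was called over all genes, and adjusted over the list alone 1 root marker rose. The other lists tested did not pass, and 25 of 27 did not in all.

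The next comparison asks the same of far-red light, where 236 probe sets passed the test and 88.6% of them were higher under DEX. AT2G41990 again rose most, 4.78-fold, from 6.62 ± 0.18 to 8.88 ± 0.10 (SD, n = 4 each; log2 change 2.26 ± 0.13, adjusted p = 2.95e-09). AT1G22910 rose 2.35-fold, AT1G32190 2.32-fold, AT2G42900 2.22-fold and AT1G51090 2.19-fold. Among named genes AT3G48970 fell most, 1.42-fold (log2 change -0.50 ± 0.09, adjusted p = 0.00238).

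The 236 called probe sets (1.04%) were 209 higher and 27 lower ones, with 15 lower without far-red DEX replicate 1 and 16 without far-red DEX replicate 3 or far-red mock replicate 1. The lower calls numbered 55 with a trended and robust variance prior and 43 without dim probe sets, and 17 with only the groups compared and 16 with only unique single-gene probe sets. Only 2 of the 27 had a fold change of at least 1.5, and 61 lower calls were made at an adjusted p under 0.1. The largest fall over all called probe sets was -0.699 on the log2 scale, on a probe set that is not named. AT3G57930 (log2 change 1.09), AT5G12050 (1.02), AT2G39130 (0.99), AT1G77480 (0.99) and AT4G35380 (0.95) were the other named genes that rose. AT3G54000 (-0.50), ATL8, a RING finger protein gene (-0.42), AT2G28200 (-0.40), AT3G61550 (-0.40), AT5G63620 (-0.39) and AT1G70990 (-0.39) fell. AT1G27670 (-0.43, adjusted p = 0.0263), B120 (-0.40, 0.0191) and AT5G64870 (-0.36, 0.0455) were called too, but the adjusted p was 0.132 for AT1G27670 without far-red DEX replicate 3, 0.0918 for B120 without far-red DEX replicate 1 and 0.177 for AT5G64870 without far-red DEX replicate 3. For 18 of the 20 genes named by size the DEX and mock arrays lay apart (2.86% by chance for genes not so chosen), the exceptions being B120 and AT5G64870. FHL had a log2 change of -0.31 ± 0.13 (adjusted p = 0.39) and HEMB1 of 0.03 ± 0.06 (adjusted p = 0.907).

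None of the 3 abscisic acid response genes was called over all genes in far-red, but all 3 rose adjusted over the list alone, with a median log2 change of 0.34 (camera adjusted p = 0.00185, and 0.0457 with an estimated correlation). COR15A and COR15B, which encode small chloroplast proteins made in the cold, had log2 changes of 0.37 ± 0.12 and 0.34 ± 0.12, and COR47, a dehydrin, 0.15 ± 0.06. The other 26 of 27 lists did not pass. Among those fixed beforehand, no member of the touch (3 genes, camera adjusted p = 0.967), auxin (5 genes, 0.92), chlorophyll (7 genes, 0.484), flavonoid (3 genes, 0.602), cell wall loosening (4 genes, 0.118) or root marker (3 genes, 0.967) list was called, over all genes or adjusted over the list alone. CML38 and STZ stood at 0.14 ± 0.14 and 0.02 ± 0.12 in far-red.

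The DEX responses in dark and in far-red were then set side by side. Higher calls were shared by 126 probe sets, against 4.9 for independent lists, so 60.3% of the higher calls in far-red were also higher in dark. AT2G41990, AT2G42900, AT1G22910, AT3G57930, AT4G35380, AT1G77480 and AT5G12050 were among the 10 largest rises of named genes in both lights. Lower calls were shared by 10 probe sets, against 0.96 for independent lists. Probe sets lower in dark had a median log2 change of -0.48 there and -0.02 in far-red, and those higher in dark had medians of 0.42 there and 0.14 in far-red. Those higher in far-red had medians of 0.46 in far-red and 0.45 in dark.

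Across all probe sets, which are not independent replicates, the log2 changes in the 2 lights correlated at r = 0.196 (rho = 0.098; r = 0.107 without far-red mock replicate 4), and at r = 0.47 over the 1436 called in either light. Opposite calls were made for 2 probe sets higher in dark and lower in far-red and 4 the other way round. The number lower in both was 6 without dark DEX replicate 3 or 4, dark mock replicate 3, or far-red DEX replicate 3 or 4, was 5 without far-red mock replicate 1 or 4, and was 4 without far-red DEX replicate 1 or 2 or far-red mock replicate 2.

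**Figure D2:**
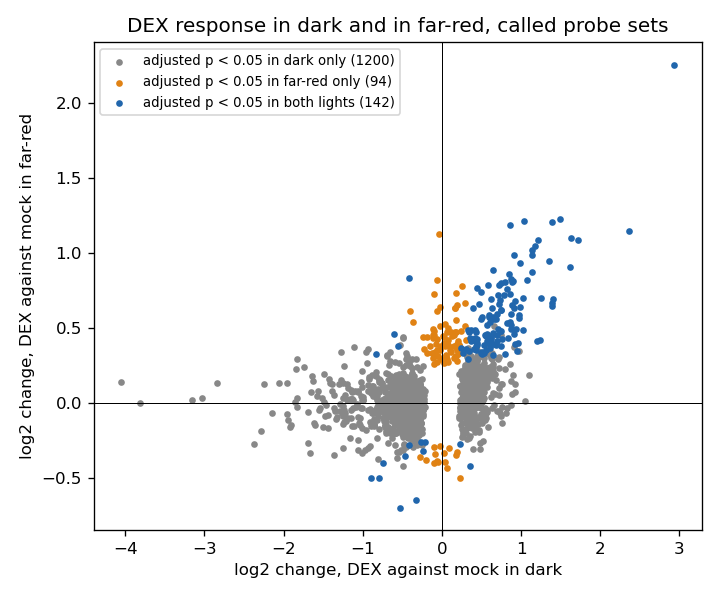
Each point is a probe set called for DEX in at least 1 light, with its log2 change against mock in dark (x) and in far-red (y); colour shows whether it was called in dark only (1200), far-red only (94) or both (142). Most points called in both lie at the upper right, and the points lower in dark spread along the horizontal line near 0 in far-red.

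The difference between the responses was tested directly. Among named genes AT1G20310 differed most: DEX changed it by -2.06 on the log2 scale in dark and by 0.14 in far-red, a difference of 2.199 ± 0.17 (adjusted p = 3.11e-07). The differences for BGLU19 (2.13), AT5G42200 (2.11), PDF2.1 (2.07) and AT2G28490 (1.88) were of the same kind, a fall in dark and a log2 change between -0.19 and 0.30 in far-red. In the other direction AT2G42900 rose more in dark (2.36) than in far-red (1.15), a difference of -1.21 ± 0.16 (adjusted p = 0.000126), and ALC, a bHLH transcription factor gene of fruit opening, had log2 changes of 1.05 in dark and 0.01 in far-red (difference -1.04 ± 0.14).

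The difference was called for 488 probe sets, with a more positive response in far-red for 386 and a more negative one for 102 (154 without dark mock replicate 2, 158 with array weights on all 16 arrays and 43 with only unique single-gene probe sets). Called differences ran from -1.211 to 4.194 on the log2 scale, the highest on a probe set that is not named. Of the 386, 344 were lower with DEX in dark and not past the test in far-red; their group as a whole had median log2 changes of -0.64 in dark and 0.08 in far-red. Further named genes with a positive difference were AT4G02170 (1.83), AT2G43590 (1.83), AT2G15010 (1.81), AT2G41730 (1.74) and the defensin gene LCR67 (1.68). Those with a negative one were AT1G49450 (-0.91), AT3G27270 (-0.85), SAG29 (-0.82), AT2G46060 (-0.82), AT1G62510 (-0.79), ATL8 (-0.78) and AT5G54530 (-0.77). AT2G28780 (-0.80, adjusted p = 0.0268) lost its call when 1 of several arrays was left out, most without dark mock replicate 4 (adjusted p = 0.0662).

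The touch list was the 1 of 27 lists that passed for this difference: 2 of 3 genes were called, over all genes and adjusted over the list alone (camera adjusted p = 0.00614; adjusted p = 0.187 with an estimated correlation), CML38 by 1.55 ± 0.20 and STZ by 0.84 ± 0.17. The low-oxygen list written later had a median difference of 0.56 with 12 of 21 genes called (camera adjusted p = 6.26e-30, and 0.00812 with an estimated correlation). WES1 differed by 0.60 ± 0.14 (adjusted p = 0.024), the 1 auxin gene of 5 that was called over all genes and adjusted over the list alone (camera adjusted p for the list 0.673). No gene of the chlorophyll (7 genes, camera adjusted p = 0.92), flavonoid (3 genes, 0.92), abscisic acid (3 genes, 0.0638), cell wall loosening (4 genes, 0.269) or root marker (3 genes, 0.343) list was called over all genes, and adjusted over the list alone 1 abscisic acid gene had a positive and 1 chlorophyll gene a negative difference. The difference for FHL, 0.66 ± 0.18, was not called (adjusted p = 0.0612), but it was without dark mock replicate 2 (0.82, adjusted p = 0.00201), with quantile normalisation (0.0382) and with array weights (0.0287).

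**Figure D3:**
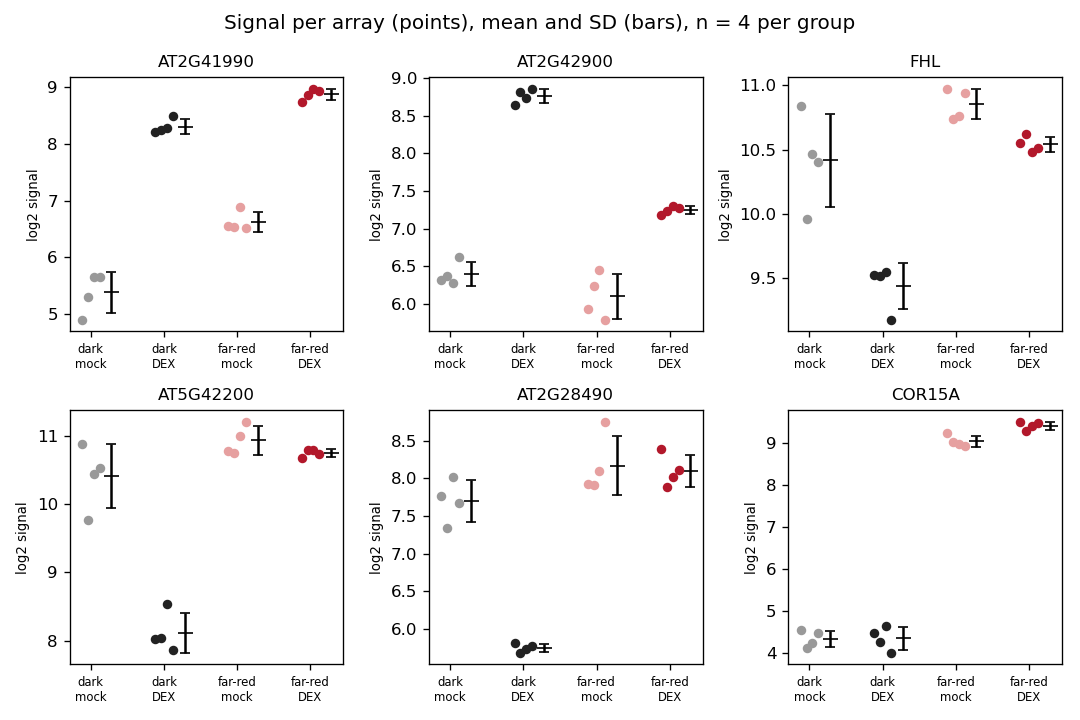
Log2 signal (y) of 6 genes on each of the 16 arrays (points) by group (x), with the mean and SD of 4 arrays beside them; the y axes do not start at 0 and differ between panels. AT2G41990 and AT2G42900 were higher under DEX in both lights, AT5G42200 and AT2G28490 were lower under DEX in dark, FHL fell in dark, and COR15A differed between lights.

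Far-red was compared with dark under mock. COR15A rose 25.9-fold in far-red, from 4.35 ± 0.19 to 9.04 ± 0.14 (SD, n = 4 each; log2 change 4.69 ± 0.12, adjusted p = 7.82e-17). COR15B rose 11.4-fold and COR27, a cold- and light-responsive gene tied to the circadian clock, 10.8-fold. AT2G25150 fell most, 10.0-fold (log2 change -3.32 ± 0.15), and the expansin gene EXPB1 fell 5.75-fold and the pectin methylesterase gene PME61 6.65-fold. The mean signals of COR15A and JRG21 (3.71) in dark mock and of AT2G25150 in far-red mock (4.24) lay under the lower quartile of all probe sets, which was 4.41 to 4.497 on the mock arrays. The files give no background, so it is unknown whether these signals were above it, and the folds are lower limits if they were not.

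Of 22746 probe sets, 8782 (38.6%) were called, 4050 higher and 4732 lower in far-red. AT3G57020 (log2 change 4.11), AT3G28220 (3.96), AT2G43620 (3.53), AT2G29360 (3.301), the jasmonate-regulated gene JRG21 (3.20), AT1G15010 (3.06) and the thionin gene THI2.2 (3.02) also rose. AT4G22460 (-3.07), AT1G30760 (-2.78), AT1G53690 (-2.74), AT1G67750, a pectate lyase gene (-2.45), AT1G12010, an ACC oxidase gene of ethylene synthesis (-2.38), AT5G24580 (-2.37) and AT5G50915 (-2.36) also fell. For all 20 genes named by size the far-red and dark arrays lay apart (2.86% by chance for genes not so chosen). FHL and HEMB1 rose by 0.44 ± 0.13 (adjusted p = 0.00914) and 0.38 ± 0.06 (adjusted p = 3.14e-05).

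Of 11 nuclear genes of photosynthesis, 10 rose in far-red under mock, with a median log2 change of 1.15 (camera adjusted p = 4.39e-11; adjusted p = 0.0885 with an estimated correlation). PSAN of photosystem I rose by 1.91, RCA, which activates RuBisCO, by 1.46 and SBPASE of the Calvin cycle by 1.19. Of 69 plastid-encoded genes 41 rose and 2 fell (camera adjusted p = 2.02e-07; adjusted p = 0.567 with an estimated correlation), with psbA up by 2.31 and psaB by 1.01. All 4 measured genes of the 15 listed for cell wall loosening fell, over all genes and adjusted over the list alone: EXPB1 (-2.52), XTH19 (-0.98), EXPA8 (-0.97) and XTH33 (-0.24) (camera adjusted p = 0.000268, and 0.0267 with an estimated correlation). The wider list of 18 expansin genes did not pass, with 6 that fell and 2 that rose (camera adjusted p = 0.499). Of 22 TBL genes, a family that acetylates cell wall polymers, 11 fell, TBL41 by 2.32 and TBL38 by 1.36 (camera adjusted p = 0.00162, and 0.0267 with an estimated correlation).

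Of the 3 abscisic acid response genes, COR15A and COR15B rose and COR47 stood at -0.02 ± 0.06 (2 of 3 also adjusted over the list alone; camera adjusted p = 0.0016, and 0.0267 with an estimated correlation). COR15A and COR15B are also known as cold-response genes. Among 7 chlorophyll synthesis genes 4 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.505): CHLM rose by 0.32, HEME1 by 0.25, and PORB, a protochlorophyllide oxidoreductase, fell by 1.12. The touch list had 2 genes that rose, STZ (0.85) and CML38 (0.71), and 1 that fell, WRKY53 (-0.75), with the same counts adjusted over the list alone (camera adjusted p = 0.505). Of 3 flavonoid genes 1 rose, UGT78D2 (0.75), and 2 did adjusted over the list alone (camera adjusted p = 0.203). Of 5 auxin genes IAA29 rose by 0.94 and WES1 fell by 0.74, with 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.67). None of 3 root marker genes was called either way (camera adjusted p = 0.762). In all 5 of 27 lists passed, and 3 with an estimated correlation. A ribosomal RNA probe set was 0.52 higher on the log2 scale in the far-red mock arrays (exact permutation p = 0.0286, adjusted p = 0.153).

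Far-red was also compared with dark under DEX. COR15A rose 33.3-fold (log2 change 5.06 ± 0.12), AT3G57020 23.8-fold, AT3G28220 22.6-fold and AT1G15010 19.7-fold. Among named genes AT1G30760 fell most, 9.10-fold (-3.19 ± 0.14), followed by AT2G25150 (-3.12), AT1G53690 (-3.10), AT1G12010 (-2.95) and AT4G22460 (-2.91). The mean signals of COR15A (4.35) and JRG21 (3.73) in dark and of AT2G25150 in far-red (4.33) again lay under the lower quartile, 4.38 to 4.48 on the DEX arrays, so the same limit holds for their folds.

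There were 9027 calls (39.7%), 3972 higher and 5055 lower in far-red. Their log2 changes ran from -3.706 to 5.074, both on probe sets that are not named. Higher calls were shared with the mock comparison by 3033 probe sets and lower calls by 3829, and 41 were called in opposite directions; the log2 changes correlated at r = 0.902 across probe sets. The other named genes that rose were COR15B (3.99), AT2G43620 (3.63), AT1G65490 (3.47), JRG21 (3.44), COR27 (3.37) and THI2.2 (3.24). AT5G45950 (-2.77), EXPB1 (-2.76), TBL41 (-2.66), AT5G24580 (-2.64) and PME61 (-2.56) fell. FHL rose by 1.101 ± 0.13 (adjusted p = 4.25e-07) and HEMB1 by 0.44 ± 0.06. In all 20 genes named by size the far-red and dark arrays lay apart (2.86% by chance for genes not so chosen).

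Among 11 nuclear genes of photosynthesis 10 rose and 1 fell under DEX (camera adjusted p = 5.15e-09; adjusted p = 0.15 with an estimated correlation), PSAN by 1.80 and RCA by 1.46 upward. The ribosomal RNA probe set was 0.43 higher in the far-red DEX arrays (exact permutation p = 0.0571, adjusted p = 0.183). Plastid-encoded genes rose in 38 cases and fell in 2 of 69 (camera adjusted p = 1.11e-06; adjusted p = 0.623 with an estimated correlation). The 4 measured cell wall loosening genes fell, also adjusted over the list alone, with a median of -1.12 (camera adjusted p = 0.00016, and 0.0282 with an estimated correlation). Of the 18 expansin genes 7 fell and 1 rose (camera adjusted p = 0.229). Among 22 TBL genes 11 fell and 1 rose (0.00441, and 0.0282 with an estimated correlation). Of 9 XTH genes, which remodel xyloglucan, 6 fell, XTH26 by 1.39 and XTH19 by 1.15 (camera adjusted p = 0.014; adjusted p = 0.305 with an estimated correlation); under mock 6 fell and 1 rose (0.0595). Of 3 abscisic acid response genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.000539, and 0.0282 with an estimated correlation).

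The remaining lists fixed beforehand did not pass under DEX. Of 3 touch genes 2 rose, CML38 (2.26) and STZ (1.68), and WRKY53 fell by 0.96 (camera adjusted p = 0.208). Of 7 chlorophyll genes HEMB1 and HEME1 rose and PORB fell (0.873), of 3 flavonoid genes UGT78D2 rose (0.222), of 5 auxin genes IAA29 rose and HAT2 and GH3.1 fell (0.873), and none of 3 root markers was called (0.871 with an estimated correlation). Each of these lists had the same counts adjusted over the list alone.

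A last comparison asks whether DEX moved light-regulated probe sets as far-red light does. The 4050 probe sets higher in far-red had a median DEX change of 0.04 in dark and -0.03 in far-red on the log2 scale, and the 4732 lower in far-red had medians of 0.00 and 0.00. Because the mock arrays enter both sides, the mock arrays were split, with one part choosing the probe sets and the other compared with DEX. The medians for probe sets higher in far-red were then 0.02 and 0.00 in dark and -0.01 and -0.01 in far-red, and those for probe sets lower in far-red were 0.00 and 0.01 in dark and -0.01 and -0.04 in far-red.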

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

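The tests on seed maturation genes, on low-oxygen genes, on single arrays and on scaling were chosen only after the patterns they bear on had been seen. Their limits were written before the values they measure were seen, except in the test of bright seed maturation genes, 1 of which had been seen; leaving that gene out was chosen after the values were seen.

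Of 65 named genes examined for a difference of the DEX response between far-red and dark, 28 passed the test of that difference (adjusted p from 3.11e-07 to 0.0383), but 20 of these were named for being the largest called differences, and over all probe sets 2.15% were called. On the log2 scale the response was more positive in far-red for AT1G20310 (2.199), BGLU19 (2.131), AT5G42200 (2.105), PDF2.1 (2.068), AT2G28490 (1.884), AT4G02170 (1.833), AT2G43590 (1.829), AT2G15010 (1.809), AT2G41730 (1.736), LCR67 (1.682), PAP85 (1.42), AT1G15010 (1.243), AT1G51090 (1.172), AT1G65490 (0.648) and AT3G28220 (0.541). It was more negative in far-red for AT2G42900 (-1.211), ALC (-1.04), AT1G49450 (-0.906), AT3G27270 (-0.85), SAG29 (-0.824), AT2G46060 (-0.818), AT2G28780 (-0.795), AT1G62510 (-0.785), ATL8 (-0.782), AT5G54530 (-0.765), AT3G48970 (-0.727), AT1G11700 (-0.722) and AT5G63620 (-0.436).

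In 20 of 288 groups of 4 arrays, 1 array lay far from the other arrays of its group, against 14.4 by chance, which sets apart about 1 in 20 groups. The number given is the gap to the nearest array as a share of the group's range. Among far-red mock arrays, replicate 3 was high for AT2G41990 (0.911) and low for AT2G28780 (0.912), replicate 4 was high for BGLU19 (0.833), AT2G41730 (0.844) and AT2G25150 (0.951), and replicate 2 was high for AT2G39130 (0.859) and AT5G63620 (0.835) and low for AT3G61550 (0.865). Among dark DEX arrays, replicate 4 was low for PDF2.1 (0.878), AT4G22460 (0.953) and FHL (0.91) and high for AT3G54000 (0.953), and replicate 3 was high for AT2G41730 (0.838). Among dark mock arrays, replicate 2 was low for AT1G20310 (0.933), replicate 1 was high for AT2G28200 (0.879), and replicate 4 was high for AT5G64870 (0.902) and AT2G43620 (0.843). Among far-red DEX arrays, low values were those of replicate 2 for AT2G15010 (0.891), replicate 4 for EXPB1 (0.841) and replicate 1 for AT3G27270 (0.96).

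The first pattern is the set of probe sets lower with DEX in dark and not in far-red, for which a single dark array is argued against, since leaving out any 1 of the dark arrays left at least 639 lower calls, against 809. Handling or low oxygen during treatment that the dark DEX samples had less of stays open. The 21 low-oxygen genes not seen before had a median change of -0.524, all of them negative and little beyond the limit of -0.5. The list was written after 5 of its genes had been seen in these same arrays. Genes that move with those 5 would fall here whatever the cause, so meeting the limit is not independent support. An effect of FHY3-GR on these genes would also give the same values. A lower share of late-germinating seeds stays open, with a median of -0.412 over 26 seed maturation genes, and so does a single source of seed RNA diluted by 1 factor, since 71.4% of 7 bright seed genes changed within 0.5 of their median and 83.3% without AT2G28490, which had been seen, so that 1 seen gene decides whether the limit of 80% is met. The 7 genes ran from -1.954 to -0.088 around a median of -0.569. Of the genes not seen before M17 (-1.549 ± 0.22) and OLEO3 (-0.088 ± 0.10) lay apart by more than their standard errors, which goes against 1 factor for these genes. The share with or without the seen gene cannot decide, because a limit of 0.5 is nearly as wide as the median change and counts OLEO3, which hardly changed. A response to FHY3-GR that differs between dark and far-red, which the design names, stays open as well and was not tested apart from these.

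The second pattern is the set of probe sets higher with DEX in both lights. The lowest count under another scaling was 120, against 126, so differences in centring left in the deposited values account for few of these calls. The arrays had been brought to nearly the same level before deposit, so rescaling them could change little. The count therefore cannot decide whether the DEX and mock arrays were centred differently by the normalisation before deposit, and that stays open. A response to dexamethasone itself and one to the fusion protein cannot be told apart, because 0 arrays of seedlings without the GR fusion are in this design.

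For the DEX and the light contrasts, chance as the source of the number of calls was made less likely, but not excluded, by splits of the arrays. For each DEX and each light contrast 1 of 35 splits, the real one, gave as many calls. These were 1342 for DEX in dark (highest other split 1) and 236 for DEX in far-red (highest other 0). They were 8782 for light under mock and 9027 for light under DEX (highest other 0 for each). That share is the smallest that 4 against 4 arrays allow. Every other split mixed both groups, which puts the response into the spread within groups. The low counts of those splits therefore add nothing to that share. For the difference of responses (488 calls, highest other split 736) the splits do not decide, although 4 of 100 drawn, the real one included, gave as many, and this reading was chosen after they were seen. The 93 that mixed DEX and mock arrays in both lights put the DEX response itself into the spread within groups and gave 0 calls, and of the 6 others that kept the groups of 1 light whole, 3 gave at least 488.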

How the results depend on the processing

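All alternatives were planned, except that some gene lists, and leaving a seen gene out of the test of bright seed maturation genes, were added later. Of 140 calls of named genes 136 were kept under each alternative run on them and none turned direction. Most of these genes were named for the size of their called change, which by itself makes a call likely to be kept. The fold change limit was run on counts only. The falls named for DEX in far-red, the largest -0.502 on the log2 scale, are smaller than 1.5-fold. Of 15 calls of lists 7 were kept, and 7 of the 8 others were lost only with an estimated correlation, as given beside them. The remaining one, nuclear photosynthesis for DEX in dark, was also lost with fry (adjusted p = 0.185), without dim probe sets (0.0836), with array weights (0.0524), without dark DEX replicate 2 (0.381) and without dark mock replicate 4 (0.261). Asking also for a fold change of at least 1.5 gave 420 calls for DEX in dark, 69 for DEX in far-red, 2807 for light under mock, 3249 for light under DEX and 322 for the difference of responses, which had 775 at an adjusted p under 0.1; stricter or looser limits do this by construction. With only unique single-gene probe sets, so with fewer tested, there were 664, 125, 4614, 4747 and 240 calls, 62 higher in both lights and 4 lower in both. Fitting only the groups compared left 4 lower in both, B120 at an adjusted p of 0.0713 and AT5G64870 at 0.114; the cause was not tested. Without 1 array, calls ran from 1065 to 1439 for DEX in dark, 161 to 216 for DEX in far-red, 8008 to 8569 for light under mock, 8286 to 8546 for light under DEX, 368 to 668 for the difference of responses, 106 to 126 for higher in both and 4 to 12 for lower in both, with r from 0.107 (without far-red mock replicate 4) to 0.226. Lower in both was 6 without dark DEX replicate 3 or 4, dark mock replicate 3, or far-red DEX replicate 3 or 4, 5 without far-red mock replicate 1 or 4, and 4 without far-red DEX replicate 1 or 2 or far-red mock replicate 2.

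Lower calls for DEX in far-red (27) were 15 without far-red DEX replicate 1 and 16 without far-red DEX replicate 3 or far-red mock replicate 1, and ran from 15 to 36 without 1 array; negative differences of responses (102) ran from 76 to 154, the latter without dark mock replicate 2. With a trended prior there were 55 lower calls in far-red, without dim probe sets 43 and with only the groups compared 17, and with array weights 158 negative differences. The cause was not tested. Asking also for a fold change of at least 1.5 left 2 lower calls in far-red and 39 negative differences. An adjusted p under 0.1 gave 61 and 225. Calls lost without 1 array, with the adjusted p, were those of B120 (0.00494 to 0.0918 over its alternatives; far-red DEX replicate 1 0.0918, 2 0.0719, 4 0.0686, far-red mock replicate 1 0.0819, 2 0.0634, 4 0.0536), AT5G64870 (0.0152 to 0.177; far-red DEX replicate 1 0.0988, 2 0.156, 3 0.177, far-red mock replicate 1 0.0956, 2 0.115, 4 0.152), AT1G27670 (0.00766 to 0.132; far-red DEX replicate 1 0.0711, 3 0.132, far-red mock replicate 1 0.113, 2 0.0657, 3 0.053) and, for the difference of responses, AT2G28780 (0.00158 to 0.0662; dark DEX replicate 3 0.0568, 4 0.0555, far-red DEX replicate 4 0.0605, dark mock replicate 1 0.0627, 4 0.0662, far-red mock replicate 1 0.0634, 2 0.065). Calls gained were FHL for the difference of responses (0.0382 with quantile normalisation, 0.0287 with array weights and 0.00201 without dark mock replicate 2, in a range up to 0.121) and, for DEX in dark, LHCB4.1 with a trended prior (0.0283, up to 0.292) and PSAE-1 without dark mock replicate 2 (0.0371, up to 0.463). Uncalled changes near 0 changed sign for COR47 under mock (0.018 with median centring, -0.037 to 0 without 1 array), WRKY53 (-0.049 to 0.108) and HEMB1 (-0.059 to 0.004) for DEX in dark; the cause was not tested.

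With the replicate number as a block there were 1412, 236, 8919, 9095 and 538 calls, 124 higher in both and 10 lower in both, and of 171 results for named genes and lists, called or not, 0 changed direction or side of the threshold. Same-numbered arrays deviated together (r over 0.1) in 1, 1, 2 and 0 of 4 numbers for DEX in dark, DEX in far-red, light under mock and light under DEX, and as many correlated best with their own number. Replicate 1 was among them for DEX in dark (r = 0.2), DEX in far-red (0.216) and light under mock (0.103). Most numbers thus showed no pairing, but a batch shared by same-numbered arrays is not excluded. The files give no signal over background, so the limit it sets is unknown.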

Other observations

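The seed maturation and low-oxygen lists, and every test on them, were chosen only after the named genes had been seen; the tests here are on members not seen before, adjusted over 10 tests, but the mean signals also cover 2 seed maturation and 5 low-oxygen genes that had been seen. In far-red against dark under mock, 21 of 26 seed maturation genes rose and 1 fell (median log2 change 0.77, camera adjusted p = 4.85e-08; adjusted p = 0.0777 with an estimated correlation), and under DEX 20 rose and 1 fell (median 0.90, 4.93e-12, and 0.0467 with an estimated correlation). Over 28 measured genes the mean log2 signal was 6.05 ± 0.10 in dark mock, 5.53 ± 0.08 in dark DEX, 6.61 ± 0.17 in far-red mock and 6.49 ± 0.13 in far-red DEX (SD, n = 4 each). For DEX in far-red no seed maturation gene was called (median -0.10, camera adjusted p = 0.0187; adjusted p = 0.458 with an estimated correlation), and for the difference of responses 4 were (median 0.30, 3.3e-08; adjusted p = 0.0777 with an estimated correlation).

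Of 21 low-oxygen genes, 19 rose and 2 fell in far-red under DEX (median 0.69, camera adjusted p = 3.82e-11; adjusted p = 0.0634 with an estimated correlation), against 8 and 3 under mock (median 0.18, 0.0486; adjusted p = 0.489 with an estimated correlation). For DEX in far-red 1 rose (median 0.02, 0.0473; adjusted p = 0.489 with an estimated correlation). Their mean signal over 26 measured genes was 10.80 ± 0.19 in dark mock, 10.02 ± 0.12 in dark DEX, 11.01 ± 0.04 in far-red mock and 11.04 ± 0.02 in far-red DEX (SD, n = 4 each). The lists share 0 genes, and 1 low-oxygen gene, CML38, is also in the touch list.

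Poly-A control transcripts had a mean log2 signal of 8.07 ± 0.13 in dark mock, 7.73 ± 0.31 in dark DEX, 7.21 ± 1.101 in far-red mock, where 1 array stood at 5.60, and 7.77 ± 0.20 in far-red DEX (SD, n = 4 each). Exact permutation p values were 0.0857 for DEX in dark, 0.457 for DEX in far-red, 0.0571 for light under mock and 0.857 for light under DEX.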
